A study of Apis mellifera with 48 samples.

How the data were processed

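Polyadenylated RNA from the mushroom bodies of 48 individual honey bees (Apis mellifera) was sequenced, 1 library per bee. The mushroom bodies are paired brain structures of insects that take part in learning, memory and the integration of sensory input. Per the labels' protocols, the heads were frozen in liquid nitrogen before dissection, and libraries were made with a directional kit, so that the strand of a transcript was kept. The bees were drones, which are haploid males, and workers, which are diploid females that do not normally reproduce. Each sex was collected at 3 pm, when the bees were active and about to leave the hive, and at 9 am, when they were inactive. The 4 groups held 12 bees each. Activity and clock time were the same division of the bees, so no comparison separates them.

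The deposited values are raw read counts per gene, and the authors' normalization is not part of them. Per the submitters' processing notes, the tools were CASAVA 1.8.2, Trimmomatic 0.30, TopHat2 2.0.10, SAMtools, HTSeq 0.5.4 and edgeR 3.4.2, with no role or order given. The counting mode, the strand setting and the rule for reads on overlapping genes are not given in the sources used here. Ambiguous reads and reads with several alignments were given to no gene. Reads of overlapping or near-identical genes could therefore be lost, or be given to 1 of them, and such genes are uncertain. Each file listed 15314 gene identifiers and 5 summary rows for reads that were given to no gene. The summary rows were left out of library sizes and tests. Reads outside annotated genes made up 28.0% ± 1.73 (SD, n = 48) of all entries in a file, ambiguous reads 0.909% ± 0.0829, and reads with several alignments 2.68% ± 0.181.

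The gene identifiers came from an older gene set than the name table at hand, which belongs to the assembly Amel_HAv3.1. Of the 15314 identifiers, 0 matched an entry of that table, and the files do not pair identifiers with names. Genes are therefore given by identifier, without names, functions or positions. The 24 gene lists fixed before the data were examined (among them clock, immediate early, neuropeptide, amine and sex determination genes, and markers of other tissues) could not be matched to any gene and were not tested. The rule for named genes, also fixed beforehand, asked for a name. Its lowest-p part was kept in reduced form once no name was found. For each comparison the 2 genes with the lowest p in each direction are given, among genes past the threshold with a mean log2 CPM of at least 1.

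Genes with too few reads were removed with the filterByExpr function by group, which left 11167 genes, and 1074 genes had no read in any library. Library sizes were scaled by TMM. A single quasi-likelihood model of the 4 groups with colony as a covariate was fitted to all 48 libraries with edgeR 4.0.16 in R 4.3.3. Unless another fit, test or set is named beside it, an adjusted p comes from this two-sided test with Benjamini-Hochberg adjustment over the 11167 genes. Fits with other libraries or thinned counts were adjusted over the genes left by their own filter. The threshold was 0.05 throughout. Standard errors of log2 fold changes were taken as the fold change divided by the root of its F statistic. CPM values are counts relative to the scaled library size, on the usual CPM scale, and log2 CPM for principal components and scores used a prior count of 2. Colony and sequencing pool came from the labels, which give 3 colonies headed by unrelated, naturally mated queens and 7 pools. Each bee is a separate animal, but bees of 1 colony share a queen and a hive.

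The comparisons were the activity response of workers, the activity response of drones, their average, their difference (worker response minus drone response), the difference between drones and workers averaged over both times, and the genes past the threshold in the same direction in workers and drones. The overlap was tested with a one-sided Fisher's exact test over the genes tested. The worker and drone responses share no library.

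The script was tested on simulated counts with the real means, dispersions and library sizes and 200 changed genes. Each gene had 1 mean over all bees, without sex or colony differences, and genes were drawn independently. Only genes with a mean of at least 1 CPM were changed. In the simulated worker response, run on 11101 genes, 46% of genes changed by 0.5 on the log2 scale were recovered, 82% at 1, 94% at 1.5 and 96% at 2, and 4.22% of the calls were false. In the simulated difference between the responses, run on 11117 genes, the recovered shares were 24%, 60%, 84% and 94% in the same order, and 2.24% of the calls were false. Variation shared among genes was not simulated, so the shares recovered and falsely called need not hold for the real counts. Gene reads per library ran from 6.69 to 27.1 M, which sets the precision for weakly expressed genes.

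Alternatives fixed before the data were examined were size factors in place of TMM, no low-count filter, DESeq2 1.42.0, limma-voom (limma 3.58.1), no colony term, pool terms, the replicate number as a block, the libraries of 1 sex alone, each colony left out, and the only library of pool 7 left out. Added after the data had been seen were 2 surrogate variables (sva 3.50.0), each library left out in turn, thinning of every library to the smallest total, and the overlap of the responses from fits of 1 sex each. Responses of single colonies, also added then, were estimated in fits with a mean for each group and colony, or for colony 3 and for the other colonies together. No pair of libraries within a group was near-identical. The chi-square per gene of the 66 pairs in each group was at least 11.3, far above the value near 1 of a library sequenced again.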

Results

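Gene expression was measured in the mushroom bodies of 48 single honey bees, in 12 active workers at 3 pm, 12 inactive workers at 9 am, 12 active drones at 3 pm and 12 inactive drones at 9 am. The series addresses how brain gene expression relates to reward-related behaviour that is learned, as in the foraging of workers, or instinctive, as in the flights of drones. Reads counted in genes per library were 17.3 ± 6.82 M (SD, n = 12) in afternoon workers, 15.1 ± 4.44 M in morning workers, 12.1 ± 2.31 M in afternoon drones and 13.5 ± 4.82 M in morning drones. The number of genes with at least 1 read was 12444 ± 265 over the 48 libraries.

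The colonies were spread unevenly over the groups. Afternoon workers and morning workers each comprised 5 bees of colony 1, 5 of colony 2 and 2 of colony 3. Afternoon drones comprised 2, 2 and 8 bees of colonies 1, 2 and 3, and morning drones comprised 5, 1 and 6. The first principal component held 23.7% of the variance, and sex accounted for 78.8% of it. The second component held 14.2% of the variance, and the 4 groups accounted for 14.2% of it, to which colony added 0.418%. Colony added 42.6% to the fourth component.

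**Figure D1:**
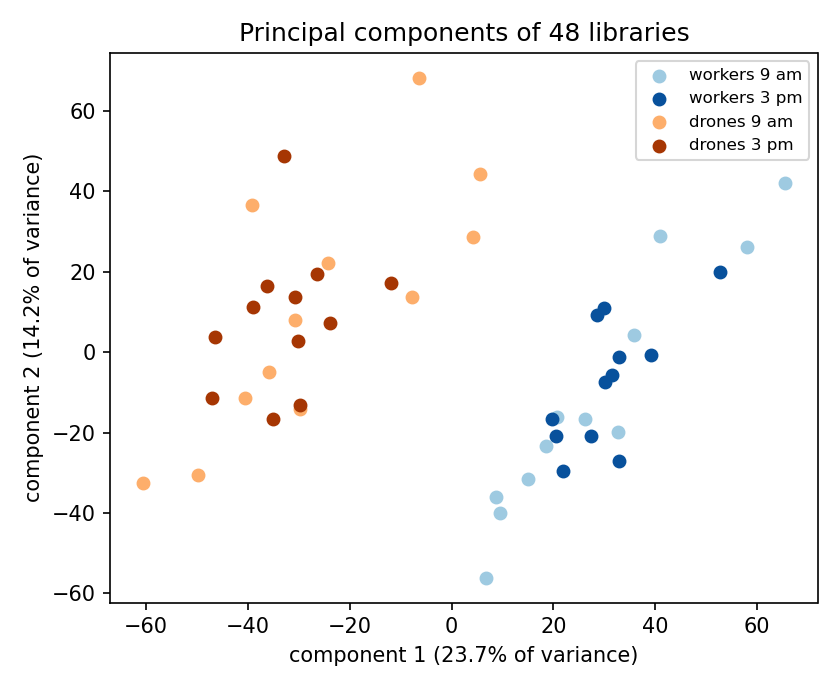
Libraries on the first and second principal components of log2 CPM, 1 point per bee, coloured by group, with the share of the variance on each axis. Drones lie towards low values and workers towards high values of component 1, which holds 23.7% of the variance, while morning and afternoon bees of a sex overlap.

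Drones against workers. The sexes differed in 5107 of 11167 genes (45.7%), of which 2701 were higher in drones and 2406 higher in workers. Most differences were small, with a median of 1.38-fold among the genes called. At least 2-fold differences were found for 560 genes higher in drones and 181 higher in workers, and at least 15-fold differences for 25 and 9 genes. The extremes on the log2 scale were 9.45 in favour of drones and -7.96 in favour of workers.

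GB43248 was the clearest worker gene, at 231 ± 119 CPM (SD, n = 12) in afternoon workers and 216 ± 97.6 CPM in morning workers, against 1.37 ± 1.12 and 0.945 ± 0.697 CPM in afternoon and morning drones. Its log2 difference, drone minus worker, was -7.76 ± 0.27 (SE; edgeR adjusted p = 6.96e-27). GB41260 was also higher in workers, at 53.1 ± 5.86 and 54.6 ± 6.86 CPM, against 2.70 ± 1.76 and 2.82 ± 2.06 CPM in drones (log2 difference -4.81 ± 0.18, edgeR adjusted p = 6.23e-26). GB47022 was higher in drones, at 142 ± 45.5 CPM in the afternoon and 106 ± 31.7 CPM in the morning, against 16.4 ± 2.88 and 16.8 ± 4.11 CPM in workers (log2 difference 2.81 ± 0.12, edgeR adjusted p = 1.14e-23). GB47020 showed a smaller and very even difference, with 293 ± 30.5 and 279 ± 59.4 CPM in drones and 109 ± 8.67 and 103 ± 13.1 CPM in workers (log2 difference 1.41 ± 0.07, edgeR adjusted p = 4.18e-22). In each of these 4 genes all 24 drones lay beyond the range of the 24 workers. Over all genes, 14 had every drone above every worker and 20 had every worker above every drone. Of the genes called without colony 1, 2 or 3, 95.8%, 89.9% and 88.7% had the same direction in the bees of the colony left out, against 74.4%, 65.1% and 59.1% of the genes not called. Without colony 1 the count was 3185.

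Active against inactive workers. This comparison asks which genes differ between workers preparing to forage and workers resting in the morning. Active workers had 184 genes higher and 74 lower, 258 in all, with a median of 1.37-fold. The larger changes were mostly decreases, as 21 genes were at least 2-fold lower and 6 at least 2-fold higher. GB53312 was 58.1 ± 10.01 CPM (SD, n = 12) in active and 38.6 ± 6.74 CPM in inactive workers (log2 fold change 0.59 ± 0.09 SE, edgeR adjusted p = 0.000384), and 10 of 12 active workers lay above all inactive ones. GB48199 was 373 ± 43.2 against 257 ± 35.3 CPM (log2 fold change 0.53 ± 0.09), with 11 of 12 above. GB49952 was 41.3 ± 7.49 CPM in active and 83.02 ± 37.7 CPM in inactive workers (log2 fold change -1.02 ± 0.16), and all 12 active workers lay below the lowest inactive one. Inactive worker 3 stood apart at 197 CPM, where the others had at most 93.6 CPM. The log2 fold change of GB49952 ran from -1.08 to -0.81 over 48 fits that each left out a library, and passed in all of them. GB53588 was 14.2 ± 3.16 against 27.6 ± 10.998 CPM (log2 fold change -0.94 ± 0.15), with 8 of 12 below. The last 3 genes had the same adjusted p as GB53312.

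Of the 12, 63 and 140 genes called without colony 1, 2 or 3 and also tested in the fit of all bees, 12, 48 and 100 (100%, 76.2% and 71.4%) had the same direction in the bees of the colony left out, against 66.3%, 67.2% and 58.9% of the genes not called. The number of genes moved with the libraries used. It was 12 without colony 1 (where GB53312 and GB49952 no longer passed, edgeR adjusted p = 0.185 and 0.10002), 64 without colony 2, 140 without colony 3, 121 with pool terms and 104 without worker_3pm replicate 4, the only library of pool 7. Leaving out worker_3pm replicate 3, 7 or 9 gave 126, 165 or 150, and leaving out worker_9am replicate 2, 3, 8 or 9 gave 128, 89, 161 or 139. It was 170 after thinning to equal depth and rose to 846 with 2 surrogate variables. With size factors in place of TMM the share of higher genes was 61.2%, against 71.3%. That share was 51.4% without colony 3 and 56.7% without worker_3pm replicate 4, but 77.6% with limma-voom and 83.3% without colony 1.

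Active against inactive drones. The same question was put to drones about to fly. Active drones had 295 genes higher and 146 lower, 441 in all, with a median of 1.45-fold. Here the larger changes were mostly increases, as 77 genes were at least 2-fold higher and 14 at least 2-fold lower. GB50091 rose from 99.6 ± 44.8 CPM (SD, n = 12) to 685 ± 401 CPM (log2 fold change 2.60 ± 0.32 SE, edgeR adjusted p = 6.76e-07). GB47136 rose from 217 ± 38.4 to 495 ± 150 CPM (log2 fold change 1.11 ± 0.13, edgeR adjusted p = 6.23e-07). GB44991 fell from 296 ± 54.1 to 166 ± 39.8 CPM (log2 fold change -0.86 ± 0.11, edgeR adjusted p = 7.54e-07), and GB45427 fell from 21.3 ± 8.61 to 5.53 ± 3.02 CPM (log2 fold change -1.85 ± 0.30, edgeR adjusted p = 4.76e-05). In each of these 4 genes 11 of the 12 active drones lay beyond the range of the inactive drones.

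Colony 3 gave 8 of the 12 active and 6 of the 12 inactive drones. Without colony 3 the count was 1 gene (730 at an unadjusted p below 0.05) with 2 active drones each from colonies 1 and 2 left. None of these 4 genes passed (edgeR adjusted p from 0.132 to 0.263), at log2 fold changes of 2.04 for GB50091, 0.68 for GB47136, -0.57 for GB44991 and -1.85 for GB45427. In a fit of all libraries that gave colonies 1 and 2 their own drone response, 18 genes passed for these colonies, GB50091 among them (log2 fold change 2.05, edgeR adjusted p = 0.0397). Of the 365 and 438 genes called without colony 1 or 2, 86.8% and 76.5% had the same direction in the drones of the colony left out, against 53.2% and 55.4% of the genes not called, and in colony 2 each direction rests on 1 inactive drone. The 1 gene called without colony 3 had the same direction there. From the drone libraries alone the count was 286, and with 2 surrogate variables it was 809.

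**Figure D2:**
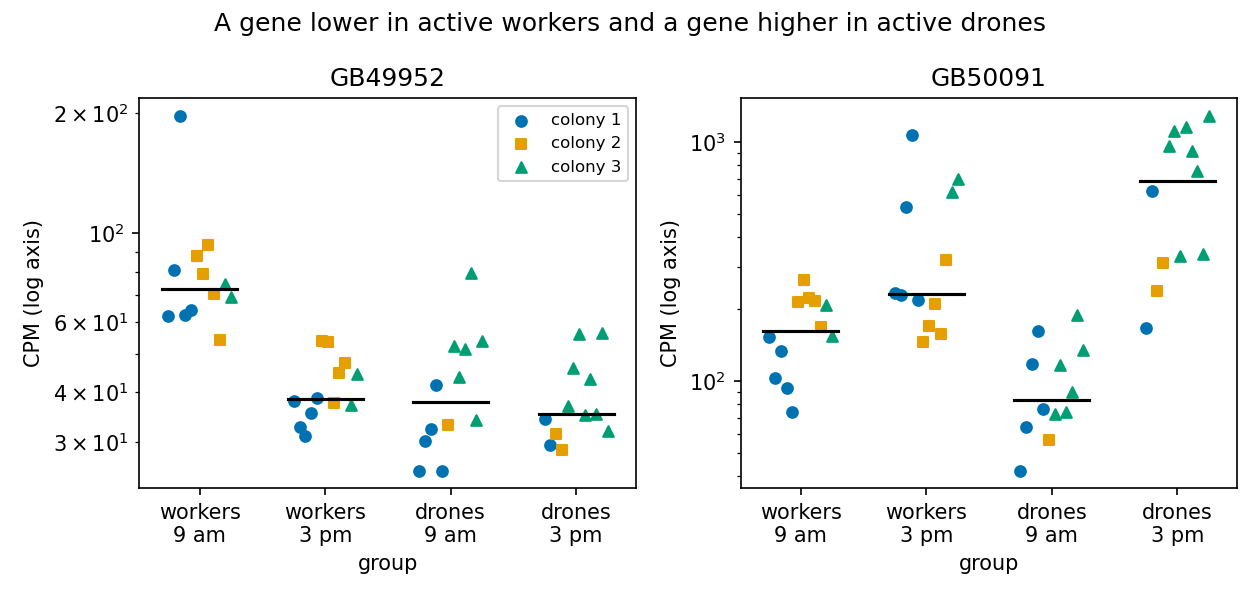
CPM per bee (log axis) of GB49952 and GB50091 in the 4 groups, with a point per bee marked by colony and a bar at the group median. GB49952 had medians of 72.6 CPM in morning and 38.4 CPM in afternoon workers, and GB50091 had medians of 83.3 CPM in morning and 692 CPM in afternoon drones.

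The response averaged over the sexes. Averaged over workers and drones, 533 genes were higher and 327 lower in active bees, 860 in all, with a median of 1.27-fold. The genes higher in active bees had a median log2 change of 0.30 in workers and 0.40 in drones, and the lower ones -0.31 and -0.33. GB47136 and GB50091 were also past the threshold on average, with log2 changes of 0.75 ± 0.09 and 1.83 ± 0.22 (SE, edgeR adjusted p = 6.37e-07 for both). Both had been chosen for their low p in drones, whose response is part of the average. In workers alone neither passed, at log2 changes of 0.39 and 1.05 (edgeR adjusted p = 0.0901 and 0.0537). The count was 202 without colony 1 and 87 without colony 3, and 1531 with 2 surrogate variables. The excess of higher genes depended on the scaling and on single libraries, as their share was 62.0% with TMM, 54.7% with size factors, 53.4% with DESeq2 and 50.5% without worker_3pm replicate 7.

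Genes shared by the responses. Of the genes past the threshold in workers and in drones, 38 were higher in both and 14 lower in both, where independent lists would share 4.86 and 0.967. The odds ratios were 10.9 and 19.4 (one-sided Fisher's exact test over 11167 genes, p = 1.22e-23 and 5.29e-13, adjusted over the 2 tests 2.44e-23 and 5.29e-13). This test treats genes as independent, so its p does not measure the variation among bees. In the opposite direction, 2 genes were lower in active workers and higher in active drones, and 0 were higher in workers and lower in drones. Of the 295 genes that rose in drones, 87.1% had a positive log2 fold change in workers, with a median of 0.21, and of the 146 that fell in drones 77.4% were negative in workers, with a median of -0.12. Of the 184 genes that rose in workers, 79.9% were positive in drones, with a median of 0.14, and of the 74 that fell in workers 85.1% were negative in drones, with a median of -0.27. Across all genes, which are not independent replicates, the log2 fold changes of workers and drones had a Pearson r of 0.19 and a Spearman rho of 0.24.

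The genes called in 1 sex also differed on average between active and inactive bees of the other, with overlap. The mean log2 CPM of the genes that rose in drones minus that of the genes that fell in drones was -0.431 ± 0.156 (SD, n = 12) in active and -0.870 ± 0.266 in inactive workers (two-sided permutation test within colonies, p = 3.0e-05, adjusted over the 2 scores 3.0e-05), and 9 of 12 active workers lay above all inactive ones. The same score for the worker genes was 1.84 ± 0.202 in active and 1.37 ± 0.256 in inactive drones (permutation p = 1.0e-05, the smallest that these permutations can give, adjusted 2.0e-05), and 6 of 12 active drones lay above all inactive ones. The shared count of 52 was 3, 16 and 0 without colonies 1, 2 and 3, 26 with pool terms, 79 with DESeq2, 152 with 2 surrogate variables and 34 from fits of 1 sex each. It was 33 without drone_3pm replicate 12, 26, 21, 30 and 30 without worker_3pm replicates 3, 4, 7 and 9, and 28, 20 and 31 without worker_9am replicates 2, 3 and 9.

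**Figure D3:**
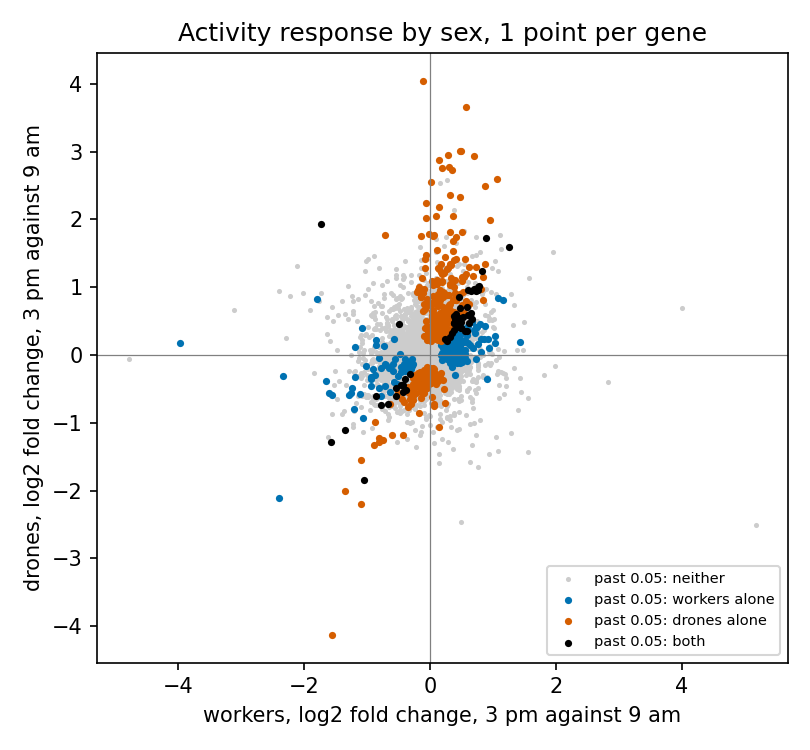
Log2 fold change of active against inactive bees in workers (x axis) and drones (y axis), 1 point per gene for 11167 genes, coloured by whether the gene was past the threshold in workers, in drones, in both or in neither. The genes past the threshold in both lie mostly in the upper right (38) and lower left (14).

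Where the responses of workers and drones differed. The test of the difference found 29 genes, and most were genes that rose in active drones with little change in workers. In 21 genes the drone response was the more positive, and all 21 were past the threshold as higher in active drones, 16 of them at least 2-fold. Their median log2 change was 1.76 in drones and -0.07 in workers. In the other 8 genes the worker response was the more positive, with medians of -0.31 in drones and 0.21 in workers.

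GB50609 had the strongest difference. It was 2200 ± 1938 CPM (SD, n = 12) in active and 115 ± 42.9 CPM in inactive drones, against 237 ± 131 and 274 ± 293 CPM in active and inactive workers. The worker response minus the drone response was -4.17 ± 0.67 on the log2 scale (SE, edgeR adjusted p = 0.00151). GB54219 was 1644 ± 1108 CPM in active and 356 ± 30.8 CPM in inactive drones, against 387 ± 115 and 410 ± 154 CPM in workers (difference -2.10 ± 0.36, edgeR adjusted p = 0.00223). Inactive worker 6 (colony 2) was the highest worker in both genes, at 1144.5 CPM of GB50609 and 874 CPM of GB54219, and raised the inactive means. The medians were 201 and 180 CPM of GB50609 and 348 and 357 CPM of GB54219 in active and inactive workers. The spread among active drones was wide because the bees fell far apart. In GB50609, active drones 1, 3 and 4 had 159, 134 and 127 CPM, within the 41.9 to 191 CPM of inactive drones, and the other 9 had 1557 to 6001 CPM. GB44887 and GB45222 had the more positive response in workers, with differences of 0.94 ± 0.20 and 0.70 ± 0.15 (edgeR adjusted p = 0.0332 and 0.0345), and stayed past the threshold in 36 and 33 of the 48 fits that left out a library. GB44887 no longer passed with limma-voom (adjusted p = 0.0647), after thinning to equal depth (edgeR adjusted p = 0.172), with the replicate block (0.0899) or without colony 2 or 3 (0.151 and 0.570). GB45222 no longer passed with the replicate block (edgeR adjusted p = 0.0899) or without colony 1, 2 or 3 (0.131, 0.101 and 0.546).

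The number of such genes was 18 without colony 1, 0 without colony 3 with edgeR (950 genes at an unadjusted p below 0.05, no other tool run on these bees), 65 with DESeq2, 10 with limma-voom and 121 with 2 surrogate variables, and between 9 and 39 when single libraries were left out. With limma-voom the response was the more positive in workers in 2 of the genes and in drones in 8. With the replicate block 12 genes were called, 0 of them with the more positive response in workers. The fits that left out a library gave 0 to 17 genes with the more positive response in workers (0 in 10 of the 48 fits) and 9 to 30 with the more positive response in drones. With size factors 12.5% of the genes had the more positive response in workers, against 27.6%. Of the 18 and 22 genes called without colony 1 or 2, 14 and 16 had the same direction in the bees of the colony left out. Of the genes not called 49.5% and 56.9% did, and in colony 2 each direction rests on 1 inactive drone.

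**Figure D4:**
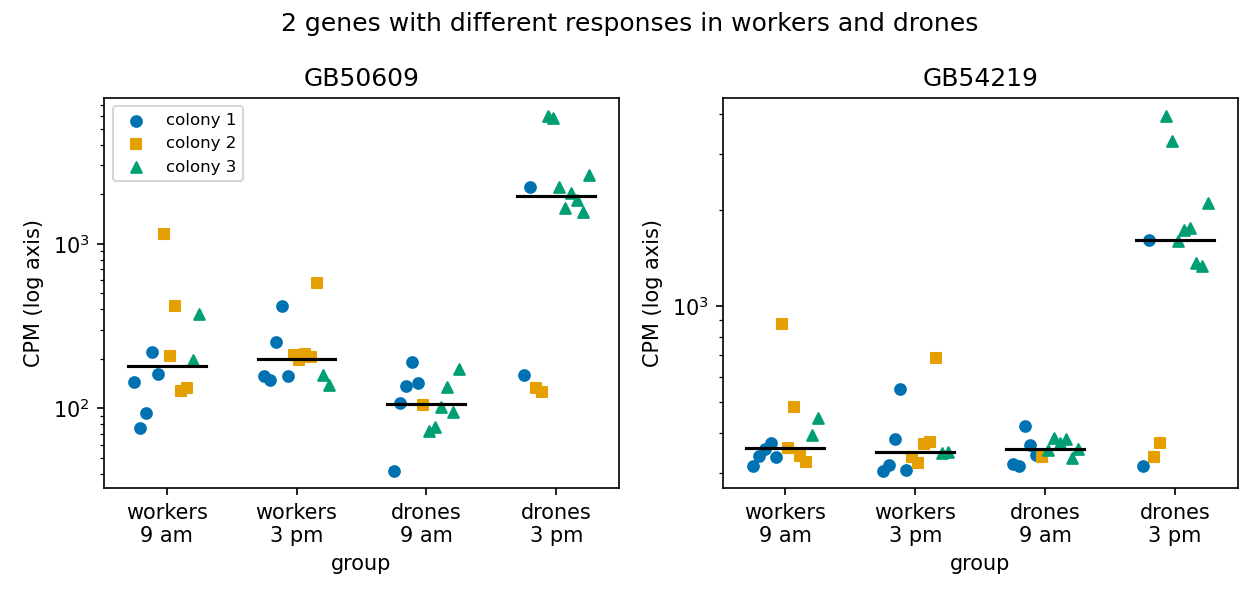
CPM per bee (log axis) of GB50609 and GB54219 in the 4 groups, with a point per bee marked by colony and a bar at the group median. All 8 active drones of colony 3 and 1 of 2 of colony 1 lie above the inactive drones, while active drones 1, 3 and 4, of colonies 1 and 2, have 159, 134 and 127 CPM in GB50609.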

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

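All tests of explanations in this part were chosen after the results had been seen.

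Workers and drones responded differently to activity in 29 genes, by a test of the difference itself. The genes given by identifier with such a difference, as worker response minus drone response on the log2 scale, were GB50609 (-4.17), GB54219 (-2.10), GB44887 (0.94), GB45222 (0.70) and GB44991 (0.67). GB44991 fell in active drones by 0.86, and its log2 change in workers was -0.18.

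Workers came mostly from colonies 1 and 2 and drones mostly from colony 3, so a colony effect on the response could have appeared as a sex effect. Unequal read depth is argued against, as 18 of the 29 remained called in the same direction after every library was thinned to 6.69 M reads. Uneven colonies between the sexes are argued against as the cause of all 29 by the responses within colony 3 alone, with 2 workers per time. There 21 genes passed over all genes tested, 9 of them among the 29 (GB50609, GB54219 and GB44991 included, with differences of -5.69, -2.82 and 1.28). The same bees had served to choose the 29, so these 9 are not an independent repeat. The bound that this count had to exceed was lowered after the count was known. The bound used before, most of the 29, left the question undecided. In colonies 1 and 2 the differences of these named genes were smaller, at -2.51, -0.96 and 0.30. Of the 21 genes, 16 kept their sign there, against 49.2% of the genes not called in colony 3. Their median in the colony 3 direction was 0.17, and 1 passed over the 21 alone. For the other 20 genes uneven colonies stay open, and over all genes tested 0 passed in colonies 1 and 2 with edgeR (1000 at an unadjusted p below 0.05, no other tool run). The sex of the bees stays open as a biological source, as does whether the differences belong to behaviour or to the hour.

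Active drones 1 (colony 1), 3 and 4 (colony 2) had levels of inactive drones in GB50609 and GB54219. Low depth is argued against, since an active drone with 9.03 M gene reads, fewer than any of these bees, had 6001 CPM of GB50609. No inactive drone was at the level of the other 9 active drones (at most 191 CPM of GB50609, against at least 1557 CPM). That would argue against an exchange of labels with inactive drones only if every active drone were high in GB50609. Active drones of colonies 1 and 2 need not be. Each drone was also scored on the other drone genes, with the bee itself left out of the fit. Drones 1 and 3 reached 52.9% and 65.5% of the way from the inactive to the active mean, above all inactive drones (at most 38.1%). Of the other 9 active drones, drones 11 and 7 (colony 3) scored lowest, at 54.5% and 61.0%. Drone 4 reached 35.7%, below inactive drones 3 and 11 (38.1% and 37.4%). A wrong label, with or without an exchange, stays open for drone 4. A weaker drone response in colonies 1 and 2 also stays open, as 13 of the 21 genes with the larger drone response passed 0.05 over these genes alone for a larger response in colony 3, but 0 of all genes tested did with edgeR (979 at an unadjusted p below 0.05, no other tool run) and the same bees had served to choose the genes. The labels do not tell how far each drone had gone towards flight, so a difference in behaviour between these bees was not tested.

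Chance was set against each count by redrawing the groups. With times redrawn within each sex, 1 of 80 splits, the real one, gave as many genes as the 258 of workers (highest other 16), 1 of 80 the 441 of drones (highest other 334) and 1 of 80 the 860 of the average (highest other 2). No drone gene passed in 59 of the redrawn splits. The split with 334 divided 14 of 24 drones as the real one does. Redrawn drone times could thus pass many genes, so adjusted p of drones need not hold their stated error. The 52 shared genes were also reached by 1 of 80 splits (highest other 0), but these splits remove the response of each sex. They cannot tell whether the worker and drone responses share more genes than independent responses would. For the 29 genes of the difference 2 of 80 splits gave as many, and the highest other gave 60. Redrawing times also removes the response common to both sexes, so this share is not a chance level for the difference alone. With sex redrawn within each time, 1 of 40 splits gave the 5107 genes (highest other 1660). Each share is under 0.05, but for the shared genes and the difference between the responses it does not decide the question asked.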

How the results depend on the processing

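The surrogate variables, the thinning, the libraries left out singly and the 1-sex fits of the overlap were chosen after the data had been seen. Of 216 results for single genes under the other alternatives, 199 kept their direction and stayed past the threshold, 17 kept their direction and no longer passed, and 0 reversed. Of those that no longer passed, 8 were without colony 3, 3 without colony 1 and 2 without colony 2. These single genes had been chosen for the lowest p in the same libraries, so most were likely to stay past the threshold. Their share therefore says little about how stable the gene counts are. In each case below the cause was not tested, except that leaving out colonies or libraries leaves fewer bees.

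Without colony 1 the counts were 12 (workers), 202 (average), 18 (difference between the responses), 3185 (sex) and 3 (shared). Without colony 2 they were 64 (workers) and 16 (shared). Without colony 3 they were 140 (workers), 1 (drones), 87 (average), 0 (difference) and 0 (shared). With every library in the fit, the drone response of colonies 1 and 2 alone had 18 genes. Pool terms gave 121 (workers) and 26 (shared), and leaving out the library of pool 7 gave 104 and 21. DESeq2 gave 65 (difference) and 79 (shared), and limma-voom 10 (difference). The libraries of 1 sex alone gave 286 (drones) and 34 (shared). With 2 surrogate variables the counts rose to 846 (workers), 809 (drones), 1531 (average), 121 (difference) and 152 (shared). Thinning every library to the shallowest gave 170 (workers), on 10346 genes.

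Leaving out each of the 48 libraries gave 89 to 305 (workers), 329 to 489 (drones), 715 to 960 (average), 9 to 39 (difference), 4828 to 5264 (sex) and 20 to 60 (shared). The difference moved by over 1.5 times without drone_3pm replicates 2, 5, 6, 8 and 12 (12, 11, 11, 15 and 12), drone_9am replicates 6, 7, 8, 9, 10 and 12 (16, 14, 15, 13, 11 and 11), worker_3pm replicates 3, 6, 7, 11 and 12 (14, 12, 10, 9 and 9) and worker_9am replicates 8 and 9 (12 and 16). GB44887 no longer passed without drone_3pm 5 or 12, drone_9am 7, 9, 10 or 12, worker_3pm 3, 6, 7, 11 or 12, or worker_9am 8 (adjusted p at most 0.0693), and GB45222 without drone_3pm 5, 6, 8 or 12, drone_9am 9, 10 or 12, worker_3pm 3, 6, 7, 9, 11 or 12, or worker_9am 8 or 9 (at most 0.0754).

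The replicate numbers were not taken to pair the bees, since not every pair with the same number correlated above 0.1. Such pairs had a median correlation of deviations of 0.0376 over 72 pairs (-0.340 to 0.49986, with 25 above 0.1), and 12 of 48 bees correlated best with their own number, where chance gives 4. Replicate numbers run in colony order within each group, and colony was left in the deviations. Bees with the same number therefore often share a colony, which the value of 4 does not allow for. With the replicate block the difference gave 12 genes, 0 of them with the more positive response in workers (adjusted p = 0.0899 for GB44887 and GB45222), and the other totals stayed within 1.5 times, but the genes lower in active drones went from 146 to 69 and those lower in both sexes from 14 to 7. The alternatives meant for the gene lists were not run, since no list could be matched to the identifiers.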

Other observations

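Of the tests in this part, those on colonies, on the second component and on reads outside genes were chosen after the result had been seen, and that on consecutive identifiers before.

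A joint test of the 3 colonies passed for 289 genes. Separate tests of each pair, adjusted on their own, passed for 311 genes between colonies 3 and 1, 59 between colonies 3 and 2 and 45 between colonies 2 and 1.

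Genes with consecutive identifiers had similar differences between the sexes. The hypothesis was that the log2 difference of a gene goes with that of the gene with the next number. Over 8710 consecutive pairs Spearman's rho was 0.260 across genes, and the highest of 1000 shuffles was 0.0379. The genes at least 4-fold higher in drones numbered 134, and 18 consecutive pairs had both members among them, where 1.25 would be expected. The activity responses showed this too, though less, with a rho of 0.132 in workers (highest shuffle 0.0334) and 0.141 in drones (0.0275), so it is not particular to sex. What consecutive numbers mean on the genome is not given in the sources used here. Duplicated genes, shared regulation and reads of 1 gene given to an overlapping model may each contribute, and none was tested.

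The second principal component, with 14.2% of the variance, was largely unrelated to group and colony. Sex alone accounted for 13.8% of this component. Its means were 8.30 and 10.7 in afternoon and morning drones, and -7.49 and -11.5 in afternoon and morning workers. Read depth is argued against, since after thinning of every library to the same total the second component had a Pearson r of 0.997 with the original one. The correlation within groups with log2 gene reads was 0.161 (Pearson; permutation p = 0.284, Spearman's rho 0.235, p = 0.120, adjusted 0.284 over 5 measures; r = 0.306 without the 2 farthest libraries and -0.133, 0.445 and 0.334 within colonies 1, 2 and 3). Of the 5 measures the TMM factor, which is computed from the same counts, had the strongest correlation (r = -0.892), followed by the ambiguous share (r = 0.670), and the share of the 20 most abundant genes had an r of 0.345 (0.649, 0.429 and -0.038 within colonies 1, 2 and 3). The share of reads outside annotated genes also went with the component, with r = -0.648 and rho = -0.647 (permutation p = 1.0e-05 for both, the smallest possible, adjusted 1.67e-05), r = -0.608 without the 2 farthest libraries and -0.718, -0.772 and -0.523 within colonies 1, 2 and 3. Pools cannot be told apart from chance here, as a share of 0.406 of 1000 random pools explained as much. A difference in RNA quality or in the tissue dissected may lie behind both, and neither was measured.

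Reads outside annotated genes made up 28.8% ± 1.57 (SD, n = 12) in active and 27.3% ± 1.66 in inactive drones, and 28.3% ± 1.44 and 27.6% ± 2.01 in active and inactive workers. The differences did not pass a permutation test within colonies (p = 0.126 in drones and 0.320 in workers, adjusted 0.252 and 0.320).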
